A study of Mus musculus with 45 samples.

How the data were processed

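RNA was sequenced from inner cell mass (ICM) and trophectoderm (TE) cells of E3.5 mouse blastocysts and from E12.5 placentas. Per the labels, each blastocyst library came from about 10 cells of 1 embryo, with ICM and TE cells separated by pipetting and told by cell shape, and was sequenced on a HiSeq X instrument. The placenta libraries were made with an mRNA kit and sequenced on a NovaSeq6000. The 45 libraries were grouped by title. The genotype label of ICSI 1 of the TE names the deletions, while its title and description name ICSI, and the title was used. On an axis set by 50 genes chosen without that library, with ICSI at 0 and DKO at 1, it stood at 0.319, the other ICSI libraries at -0.127 to 0.505 and the DKO libraries at 0.334 to 0.956. This does not decide between the labels.

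The deposited values are FPKM, made by the authors with TopHat2 2.1.1 and Cufflinks 2.1.1 on genome build mm9, per the submitters' processing notes. The gene annotation, strand setting and options are not stated. Each file held 24525 lines for 24028 symbols. The 268 symbols on more than 1 line (765 lines) were summed, and 3582 symbols were at 0 in every library. Without read counts, no limits for values of 0 can be given. A relative depth was read from the spacing of the lowest FPKM values (up to 0.5), which follows the number of mapped fragments. Genes at 1 FPKM or more numbered 9155 to 9874 in the ICM libraries, 8974 to 9617 in the TE and 11518 to 12148 in the placentas. Correlations between replicates were 0.848 to 0.955, 0.890 to 0.963 and 0.959 to 0.984. Gene order for the search along chromosomes came from GRCm38, another build than the authors used.

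Values were analysed as log2(FPKM + 1) with no further scaling. Genes were kept at 1 FPKM or more in at least 5 libraries of the ICM or TE, or 3 of the placenta. Group differences were tested by limma 3.58.1 with a moderated statistic and a mean trend, all groups of a tissue in 1 fit, on R 4.3.3 (statmod 1.5.0). P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. All ICM and TE libraries were fitted together for the TE against ICM comparison and for the test of whether the WT against ICSI difference differs between lineages. With 3 against 3 libraries an exact permutation test cannot go below 0.1, so calls rest on this model. Files were read with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) and plotted with matplotlib 3.10.9.

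Of 29 gene lists fixed in advance, 28 were tested with camera, with a preset correlation of 0.01 between members and again with a correlation estimated for each list, where at least 3 members were measured. The Y-linked list served as a check of sex. Many members of the placental lists are also expressed by other cells of the organ, so a list is not a count of cells.

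The genes named in the text follow a rule. It takes every measured member of both imprinted clusters. It takes the 6 largest changes in each direction among genes that passed, with a mean of at least 5 FPKM in the higher group and no overlap between groups. Where fewer than 3 met this, it takes the 3 with the smallest p. It takes up to 4 members with the smallest p of each list described, and Xist with the Y-linked genes. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a pseudocount of 0.1 FPKM, no filter on low values, median-ratio rescaling between libraries, library weights, the replicate number as a block, WT libraries split between comparisons, and leaving out each library in turn. Leaving out libraries in doubt, and the search for runs of neighbouring genes, were chosen afterwards. No library was left out of the reported values.

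The fits were tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. In the ICM, 29% to 39% of 2-fold and 79% to 90% of 4-fold changes were found, in the TE 49% to 54% and 85% to 91%, and in the placenta 84% to 94% and 96% to 100%. Of the simulated calls, 1.65% to 8.15% were false. A simulated list shift of 0.7 was found by camera in these comparisons and in TE against ICM. The difference between lineages was not simulated. Real data may fare worse, as other splits called up to 921 genes in the ICM, though at most 2 in the placenta. Of 81 list calls, 6 held with an estimated correlation. The search for runs found 5 of 5 planted runs and none in 5 simulations without one.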

Results

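RNA was measured in 45 mouse libraries that fall into 11 groups. The control embryos were made by intracytoplasmic sperm injection (ICSI). The semi-cloned embryos were made by injecting an androgenetic haploid embryonic stem cell in place of the sperm, and the injected cells were unmodified (WT) or carried deletions at imprinted control regions. DKO cells lacked the differentially methylated region IG-DMR (chromosome 12, 110765031 to 110769231) and that of H19 (chromosome 7, 149764920 to 149768845). IG cells lacked the IG-DMR alone, and H19 cells lacked the H19 gene body with its region (chromosome 7, 149761078 to 149774522; mm9 coordinates per the labels). At E3.5, the inner cell mass (ICM) and the trophectoderm (TE) of ICSI, WT and DKO blastocysts gave 5 libraries per group. At E12.5, the placentas of all 5 kinds of embryo gave 3 libraries per group. Without read counts, depth is known only relative to ICSI 1 of the same tissue. It ran from 0.165 to 1.67 over the ICM libraries, from 0.222 to 1.03 over the TE libraries and from 0.928 to 1.46 over the placentas. Levels below are group means in FPKM ± SD, with n = 5 per group in the blastocyst and n = 3 per group in the placenta, and log2 changes carry their SE.

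The TE was set against the ICM within ICSI embryos. Genes of the epiblast and of pluripotency stood lower in the TE. Tdgf1, the Nodal co-receptor Cripto, was at 9.30 ± 19.3 against 206 ± 51.4 FPKM, TE against ICM (log2 change -6.04 ± 0.75), and the growth factor gene Fgf4 was at 0.463 ± 0.995 against 19.5 ± 5.83 (-3.95 ± 0.41). Esrrb, a nuclear receptor of the pluripotency network, and Gdf3, a TGF-beta family ligand, fell by 2.69 and 3.79 on the log2 scale. The keratin genes Krt7 and Krt8, which mark the trophectoderm epithelium, stood at 60.8 ± 30.2 against 8.87 ± 10.3 and 1519 ± 143 against 344 ± 242 FPKM and rose by 3.22 and 2.46. Other large falls were those of Upp1, which encodes uridine phosphorylase (-5.53 ± 0.84), Spp1 or osteopontin (-5.38 ± 0.76), the threonine dehydrogenase gene Tdh (-5.33 ± 0.44), the protease inhibitor gene Timp1 (-5.17 ± 0.65) and Pyy (-4.42 ± 0.60). Tinagl1, Tmem171, the protease genes Tmprss2 and Klk7, and Hsd17b6 rose by 2.80 to 3.17. Dio3, a gene of the Dlk1-Dio3 cluster, was listed at 0 in every ICSI TE library and at 2.11 ± 1.83 FPKM in the ICM (adjusted p = 0.0151), and Igf2 stood at 4.75 ± 1.85 against 2.17 ± 1.03 FPKM (adjusted p = 0.0322).

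Of 21 measured pluripotency genes, 16 fell, and 17 fell and 1 rose when adjusted over the list alone (median -2.33; adjusted p = 5.83e-13, adjusted p = 0.0276 with an estimated correlation). Of 19 trophectoderm genes, 16 rose, and 19 did when adjusted over the list alone (median 2.18; adjusted p = 4.87e-12, adjusted p = 0.151 with an estimated correlation). Of 19 primitive endoderm genes, 13 fell and 2 rose, with 15 and 2 adjusted over the list alone; Sparc, a matrix protein gene, was at 50.3 ± 74.1 against 371 ± 123 FPKM (median -2.72; adjusted p = 9.50e-08, adjusted p = 0.196 with an estimated correlation). Among 14 genes of DNA methylation and imprint maintenance, 8 fell, also 8 adjusted over the list alone; they included Zfp57, which protects imprints, at 7.93 ± 5.08 against 74.0 ± 14.5 FPKM and the dioxygenase gene Tet1 at 2.81 ± 0.929 against 12.3 ± 5.83 (adjusted p = 0.00119, adjusted p = 0.126 with an estimated correlation). In total 2110 of 11186 genes passed the test, 888 higher and 1222 lower in the TE. With 1 library left out at a time, the calls of Tdgf1, Fgf4, Esrrb, Gdf3, Krt7, Krt8, Upp1, Spp1, Tdh, Timp1, Pyy, Sparc, Zfp57 and Tet1 held. That of Dio3 was lost without ICSI ICM 2. The call of Igf2 was lost in more than 1 such fit, among those without ICSI ICM 2 and 4 and ICSI TE 1, 3 and 4. The ICSI ICM libraries 1 and 3 had trophectoderm scores of 5.93 and 6.40, against 3.59 to 4.32 in the others.

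WT semi-cloned embryos were compared with ICSI embryos in the ICM. Saa3, a serum amyloid A gene, was higher in WT, at 59.5 ± 18.97 against 5.82 ± 4.05 FPKM (3.48 ± 0.52), as was Dmgdh, a mitochondrial enzyme gene of choline breakdown, at 7.22 ± 2.57 against 0.483 ± 0.332 (2.45 ± 0.40). H2-K1, which encodes a class I histocompatibility antigen, rose by 2.01, Ccdc43 by 1.82 and the mitochondrial protein gene Mgarp by 1.62. Snora23, a small nucleolar RNA, stood at 17.3 ± 13.2 against 0.694 ± 1.55 FPKM (3.51 ± 0.51). Tspan8, a tetraspanin gene, was lower in WT at 6.50 ± 5.41 against 224 ± 207 FPKM (-4.57 ± 0.81). Tnfrsf9, a tumour necrosis factor receptor gene, and the uncharacterised Gm10046 and 2810008D09Rik fell by 2.34, 2.16 and 1.83. The adjusted p-values of these genes ran from 0.0174 to 0.0270. Meg3, the maternally expressed noncoding RNA of the Dlk1-Dio3 cluster, was at 20.1 ± 2.82 against 4.27 ± 3.15 FPKM and did not pass the test (adjusted p = 0.0732). Igf2 was at 2.04 ± 0.681 against 2.17 ± 1.03.

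Trophectoderm genes were lower in the WT ICM as a list (median -1.73; adjusted p = 2.31e-11, adjusted p = 0.253 with an estimated correlation). No single member passed over all genes by limma, and 10 of 18 were lower when adjusted over the list alone; Id2, an inhibitor of differentiation, stood at 19.5 ± 28.2 against 234 ± 203 FPKM and Ndrg1 at 6.39 ± 4.58 against 84.3 ± 100.4. The list score was 3.08 ± 0.73 in WT and 4.88 ± 1.22 in ICSI, log2 means over the members. Nutrient transporter genes were also lower, 5 of 15 when adjusted over the list alone (median -0.58; adjusted p = 1.64e-05, adjusted p = 0.0151 with an estimated correlation). The amino acid carrier gene Slc7a5 was at 3.25 ± 1.62 against 9.79 ± 2.34. Primitive endoderm genes had a median of -0.21, with 1 of 19 lower adjusted over the list alone (adjusted p = 0.00664, adjusted p = 0.633 with an estimated correlation). Maternally expressed imprinted genes were higher, 1 of 16 over all genes and 2 adjusted over the list alone (adjusted p = 0.0134, adjusted p = 0.226 with an estimated correlation). Nap1l4, a histone chaperone gene, rose from 43.3 ± 12.6 to 105 ± 17.3 FPKM (adjusted p = 0.0203). Cell cycle genes were higher, 18 of 19 in sign with none past the threshold alone (adjusted p = 1.21e-04, adjusted p = 0.633 with an estimated correlation). With 1 library fewer the call was lost for the primitive endoderm list (ICSI 4 or WT 2 and 5). Over all 10344 genes, 13 passed, 9 higher and 4 lower. Of the 13, 2 lie in a chromosome 7 run raised in WT (Sergef to Htatip2). Without ICSI 1, 2, 3 or 5 in turn, the count was 1, 34, 0 and 27. Without WT 1, 4 or 5 it was 5, 0 and 1. It was 0 by limma without ICSI 1, 3 and 4 and DKO 1, 3 and 5, which were shallow or high in trophectoderm markers (401 genes at an unadjusted p under 0.05).

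In the ICM, DKO embryos were compared with ICSI embryos and with WT embryos, from other injected cells. Meg3 was higher in DKO than in ICSI, at 31.8 ± 25.4 against 4.27 ± 3.15 FPKM (2.48 ± 0.47, adjusted p = 0.0338). Dmgdh, H2-K1 and Snora23 were higher in DKO as well, by 2.002, 1.96 and 3.25. Scd1, which encodes a fatty acid desaturase, stood at 29.0 ± 13.4 against 7.06 ± 2.41 (1.80 ± 0.35), and Cd2, a lymphocyte adhesion gene, at 5.74 ± 2.67 against an ICSI group listed at 0 (adjusted p = 0.0260). Fgf4 was lower in DKO, at 3.26 ± 3.41 against 19.5 ± 5.83 FPKM (-2.61 ± 0.49), and Wfdc15a was lower at 2.42 ± 2.65 against 44.6 ± 15.7 (-4.10 ± 0.72). The heparan sulfate enzyme gene Hs3st1, the mitochondrial nuclease gene Endog, Gm10046 and the pepsinogen gene Pgc fell by 2.46 to 2.58. Against WT, Ldha, the lactate dehydrogenase A gene, was lower in DKO at 35.4 ± 14.4 against 229 ± 80.4 FPKM (-2.69 ± 0.32, adjusted p = 0.00189), and so was the tubulin acetyltransferase gene Atat1 at 3.19 ± 0.364 against 13.3 ± 2.12 (-1.76 ± 0.26, adjusted p = 0.0131). Meg3 differed between DKO and WT by 0.28 ± 0.47 (adjusted p = 0.948).

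Nutrient transporter genes were lower in DKO than in ICSI, 2 of 15 over all genes, and 8 lower and 1 higher adjusted over the list alone (adjusted p = 6.24e-04, adjusted p = 0.0566 with an estimated correlation). Slc7a5 fell from 9.79 ± 2.34 to 2.63 ± 0.907 FPKM and Slc38a1, a glutamine carrier gene, from 6.73 ± 1.14 to 2.02 ± 1.27. Primitive endoderm genes were lower, 6 of 19 adjusted over the list alone (adjusted p = 6.24e-04, adjusted p = 0.500 with an estimated correlation). The laminin gene Lama1 was at 4.35 ± 4.18 against 21.7 ± 8.16 and Foxa2 at 0.539 ± 1.21 against 4.24 ± 2.24. Genes of heat shock and unfolded protein stress were lower, 7 of 14 with 1 higher adjusted over the list alone (adjusted p = 0.00116, adjusted p = 0.157 with an estimated correlation). Those with the smallest p were Trib3 at 2.48 ± 2.13 against 20.9 ± 14.5 and the asparagine synthetase gene Asns at 134 ± 67.1 against 267 ± 46.6, both of the amino acid stress response. Trophectoderm genes were lower than in ICSI (median -0.80; adjusted p = 0.0261, adjusted p = 0.557 with an estimated correlation) and higher than in WT (median 1.08; adjusted p = 4.85e-06, adjusted p = 0.796 with an estimated correlation), with a DKO score of 4.03 ± 1.29 and no single member past the threshold in either. Without the libraries in doubt the second median was -0.58 and did not pass, but 3 DKO libraries were among them for high trophectoderm markers, which lowers it by construction. Stress genes were lower in DKO than in WT, 1 of 14 adjusted over the list alone (adjusted p = 8.86e-04, adjusted p = 0.248 with an estimated correlation). Single left-out libraries decided the call of the trophectoderm list (ICSI 1 and 3 or DKO 2 and 4).

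Of 10344 genes in the ICM, 34 differed between DKO and ICSI, 8 higher and 26 lower. Against WT, 2 genes differed, Ldha and Atat1, 1 of them in a chromosome 7 run raised in WT (Sergef to Zdhhc13). Without ICSI 1 to 5 in turn, the first count was 1, 13, 2, 1 and 68. Without DKO 1 to 5 it was 341, 54, 2, 6 and 5. With values rescaled it was 52, 22 higher and 30 lower. It was 0 by limma without ICSI 1, 3 and 4 and DKO 1, 3 and 5 (807 at an unadjusted p under 0.05). The DKO against WT count was 1 without WT 4, DKO 3 or DKO 4, and 4 without DKO 2. When each library was left out in turn, the call of Ldha held. The call of Atat1 was lost in more than 1 such fit, among those without WT 4 and DKO 3 and 4. Neither passed without the libraries in doubt, nor did Atat1 with values rescaled.

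In the TE, WT embryos were compared with ICSI embryos. Phlda2, a maternally expressed gene that restrains placental growth, was at 70.1 ± 109.7 against 0.482 ± 0.895 FPKM (4.32 ± 0.84), with WT 2 far above the others. Cd81, a tetraspanin gene, rose from 5.38 ± 3.66 to 86.6 ± 21.7 (3.99 ± 0.52, adjusted p = 0.00109), and Nap1l4 from 57.0 ± 14.1 to 106 ± 7.78 (0.91 ± 0.20). 3830417A13Rik, an uncharacterised gene, was at 11.9 ± 6.20 in WT and was listed at 0 in every ICSI library (adjusted p = 3.38e-05). Reep1, which encodes a protein that shapes the endoplasmic reticulum, rose by 2.92 ± 0.35, the tight junction gene Cldn6 by 2.31 ± 0.43 and Cidea, a lipid droplet gene, by 2.28 ± 0.45. Enpp1, an ectoenzyme gene of pyrophosphate metabolism, fell from 29.1 ± 5.38 to 6.32 ± 1.93 FPKM, Dusp6, a phosphatase gene of ERK signalling, from 12.9 ± 3.75 to 3.85 ± 2.96, and Tspan8 from 982 ± 202 to 406 ± 108. Hsd17b6, Rpl22l1 and the endonuclease gene Mus81 fell by 1.27 to 1.56. Igf2 stood at 4.54 ± 2.37 against 4.75 ± 1.85 and Meg3 at 1.72 ± 2.04 against 1.55 ± 1.84, neither past the threshold (adjusted p = 0.937 and 0.991).

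Maternally expressed imprinted genes were higher in the WT TE as a list, 3 of 14 over all genes and 6 adjusted over the list alone (median 0.74; adjusted p = 4.00e-05, adjusted p = 0.0264 with an estimated correlation). Phlda2, Cd81 and Nap1l4 lie in 1 raised run of 23 chromosome 7 genes, which may carry the list. Targets of p53 were higher, 7 of 15 adjusted over the list alone (median 0.80; adjusted p = 5.64e-06, adjusted p = 0.207 with an estimated correlation). Cdkn1a, the p21 gene that halts the cell cycle, was at 227 ± 87.7 against 94.0 ± 47.9 FPKM and Ccng1 at 89.6 ± 22.9 against 40.5 ± 17.8. Cell cycle genes were higher too, 3 of 19 adjusted over the list alone (adjusted p = 0.00223, adjusted p = 0.462 with an estimated correlation). Nutrient transporter genes were lower, 7 of 17 with 1 higher adjusted over the list alone (adjusted p = 0.00100, adjusted p = 0.230 with an estimated correlation). Slc7a8 was at 6.77 ± 2.57 against 26.1 ± 14.6. Trophectoderm genes had a median of -0.25 (adjusted p = 0.00461, adjusted p = 0.462 with an estimated correlation). Eomes, a trophoblast transcription factor gene, was at 11.9 ± 6.63 against 27.6 ± 11.6. In all, 68 of 9812 genes passed, 56 higher and 12 lower. Without ICSI 1, 3 or 4 in turn, the count was 33, 19 and 15. Without WT 2 or 3 it was 10 and 14. With values rescaled it was 105 (69 higher, 36 lower). In fits that lacked 1 library, the calls of Cd81, 3830417A13Rik, Reep1 and Enpp1 held. Those of Phlda2, Nap1l4, Cldn6, Cidea, Dusp6, Tspan8, Hsd17b6, Rpl22l1 and Mus81 were each lost in more than 1 such fit.

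In the TE, DKO embryos were compared with ICSI and WT embryos. Plac1, an X-linked gene of trophoblast growth, was lower in DKO at 20.7 ± 12.4 against 151 ± 65.5 FPKM (-2.85 ± 0.45), and Trib3 was lower at 1.91 ± 1.79 against 22.3 ± 15.0 (-2.93 ± 0.53). Entpd1, an ectonucleotidase gene, fell by 2.50, Abracl by 2.50, Tnfrsf9 by 2.32 and Wfdc15a by 3.498. Rpph1, the RNA of ribonuclease P, was higher at 62.2 ± 31.4 against 6.56 ± 4.56 (3.15 ± 0.60), as were the methyltransferase gene Bhmt at 23.5 ± 29.0 against 1.60 ± 1.17 (2.71 ± 0.58), Reep1 (2.37 ± 0.35) and the lysosomal gene Laptm5 (2.24 ± 0.43). AA414768 and Gm3286, both uncharacterised, rose by 2.20 and 2.19. Igf2 and Meg3 did not pass the test, at 2.71 ± 1.05 against 4.75 ± 1.85 and 3.21 ± 4.42 against 1.55 ± 1.84 FPKM. Against WT, 3830417A13Rik was lower in DKO at 0.636 ± 0.682 against 11.9 ± 6.20 (-2.92 ± 0.33, adjusted p = 6.04e-04), and the pluripotency factor gene Nanog, at 91.1 ± 23.8 against 20.6 ± 12.8, did not pass (adjusted p = 0.182). Guca1a at 42.2 ± 13.4 against 10.1 ± 5.26 and Dusp6 at 14.8 ± 6.94 against 3.85 ± 2.96 did not pass either.

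Nutrient transporter genes were lower in DKO than in ICSI, 3 of 17 over all genes and 8 adjusted over the list alone (median -0.87; adjusted p = 1.73e-06, adjusted p = 0.167 with an estimated correlation). Slc7a1, an arginine carrier gene, fell from 5.59 ± 2.46 to 0.9503 ± 0.662 FPKM, Slc38a2 from 4.06 ± 0.665 to 1.35 ± 0.914 and Slc7a8 from 26.1 ± 14.6 to 7.35 ± 4.99. Trophectoderm genes had a median of -0.26 (adjusted p = 3.62e-04, adjusted p = 0.703 with an estimated correlation). Cell cycle genes were higher, 1 of 19 over all genes and 4 adjusted over the list alone (adjusted p = 0.0175, adjusted p = 0.731 with an estimated correlation). That gene was Top2a, the topoisomerase of chromosome segregation, at 56.3 ± 15.0 against 26.6 ± 3.70. Stress genes were lower as a list, 1 of 14 over all genes, with 7 lower and 3 higher adjusted over the list alone (adjusted p = 0.0429, adjusted p = 0.723 with an estimated correlation), and this call was lost when values were rescaled between libraries. Leaving out 1 library ended the call of the cell cycle list (ICSI 1 or DKO 2) and the heat shock list (ICSI 1, 2 and 3 or DKO 4). Against WT, maternally expressed imprinted genes were lower, 2 of 14 adjusted over the list alone (median -0.55; adjusted p = 1.56e-04, adjusted p = 0.0462 with an estimated correlation). Cd81, in the chromosome 7 run named above, was at 26.4 ± 14.0 against 86.6 ± 21.7. Pluripotency genes were higher, 1 of 16 adjusted over the list alone (adjusted p = 1.56e-04, adjusted p = 0.238 with an estimated correlation), as were 2-cell-stage genes, 1 of 3 (adjusted p = 0.0385, adjusted p = 0.238 with an estimated correlation). Targets of p53 (adjusted p = 1.56e-04, adjusted p = 0.238 with an estimated correlation) and nutrient transporter genes (adjusted p = 0.00821, adjusted p = 0.300 with an estimated correlation) were lower, with no member past the threshold alone. With 1 library fewer the call was lost for the 2-cell-stage list (WT 1 and 3) and the nutrient transporter list (WT 3).

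Of 9812 genes in the TE, 149 differed between DKO and ICSI, 104 higher and 45 lower. The median of all genes stood at 0.105 on the log2 scale in this comparison, and with values rescaled between libraries 109 genes were higher and 109 lower. Without ICSI 1, 3 or 4 in turn, the count was 93, 21 and 49. Without DKO 1 to 5 it was 983, 38, 39, 65 and 39. Over the fits lacking 1 library each, the calls of Plac1, Entpd1, Tnfrsf9, Reep1 and Gm3286 held. That of Trib3 was lost without ICSI 3. The calls of Abracl, Wfdc15a, Rpph1, Bhmt, Laptm5, AA414768, Slc7a1, Slc38a2, Slc7a8 and Top2a were each lost in more than 1 such fit, among those without ICSI 1, 2, 3, 4 and 5 and DKO 2, 3, 4 and 5. Against WT, 3830417A13Rik was the only gene past the threshold, and the count was 2 without WT 1, 2 without WT 4 and 2 without DKO 3.

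Whether WT and ICSI embryos differed alike in both lineages was tested directly. By limma, 0 of 11186 genes passed this test and 536 had an unadjusted p under 0.05. The gene with the smallest p was 3830417A13Rik, whose log2 change in WT against ICSI was 2.86 ± 0.61 as TE minus ICM (adjusted p = 0.287), and Meg3 differed by -2.16 ± 0.80 (adjusted p = 0.862). As lists, trophectoderm genes (adjusted p = 1.08e-07, adjusted p = 0.573 with an estimated correlation) and labyrinth genes (adjusted p = 0.0325, adjusted p = 0.573 with an estimated correlation) differed, with medians of 1.57 and 0.55 for TE minus ICM. The WT against ICSI medians were -1.73 in the ICM and -0.25 in the TE for the first list and -0.27 and 0.22 for the second, and the second call was lost when values were rescaled. The count of genes was 1 without ICSI 2 of the ICM and 2 without ICSI 4 of the ICM.

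**Figure D1:**
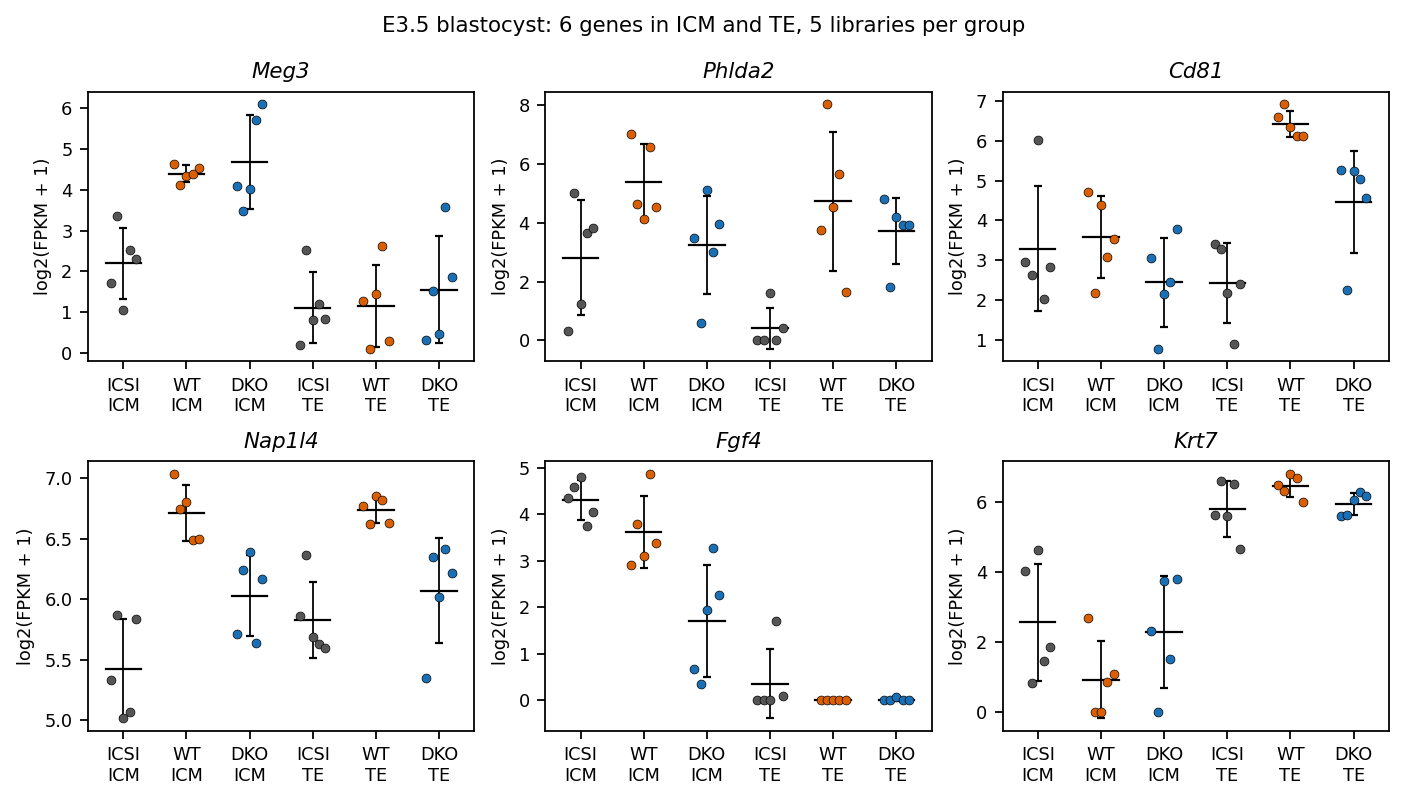
Levels of Meg3, Phlda2, Cd81, Nap1l4, Fgf4 and Krt7 in each ICM and TE library, as log2(FPKM + 1), by group; points are libraries (n = 5 per group), bars the group mean with its SD. Cd81 stood at 5.38 ± 3.66 FPKM in the ICSI TE and at 86.6 ± 21.7 in the WT TE.

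The deletions target imprinted clusters that act in the placenta, so these genes are given first for all 5 kinds of placenta. Igf2, the paternally expressed fetal growth factor gene, was at 834 ± 30.7 FPKM in ICSI and fell to 4.43 ± 2.07 in WT (-7.34 ± 0.19, adjusted p = 6.85e-11) and 3.39 ± 0.256 in IG (-7.57 ± 0.19). It stood at 859 ± 35.9 in DKO and 895 ± 95.4 in H19, neither past the threshold against ICSI (adjusted p = 0.923 and 0.861). H19, the maternally expressed noncoding RNA next to Igf2, rose from 2719.7 ± 75.7 in ICSI to 5059.6 ± 1111 in WT (0.87 ± 0.17) and 4188 ± 250.2 in IG (0.62 ± 0.17), and was at 3203 ± 125 in DKO and 2971 ± 270.3 in H19 placentas. The values do not separate the alleles. Dio3, which encodes the deiodinase that inactivates thyroid hormone, fell from 93.0 ± 33.4 to 24.6 ± 3.498 in WT (-1.82 ± 0.28) and 19.96 ± 6.81 in IG (-2.15 ± 0.28), and was at 82.7 ± 7.96 in DKO and 71.0 ± 15.3 in H19. Its antisense neighbour Dio3os fell in WT (-1.33 ± 0.27) and IG (-1.42 ± 0.27). The strand setting is not stated, so its reads are not separable from those of Dio3. Igf2os, antisense to Igf2, was at 10.8 ± 1.75 in ICSI and 0.0934 ± 0.0424 in WT and carries the same limit.

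Mirg, a maternally expressed noncoding RNA of the Dlk1-Dio3 cluster, rose from 5.84 ± 0.484 FPKM in ICSI to 14.7 ± 2.46 in DKO (1.19 ± 0.25, adjusted p = 0.0243) and 13.3 ± 3.44 in IG (1.04 ± 0.25, adjusted p = 0.0307), and was at 10.8 ± 5.34 in WT and 7.04 ± 1.11 in H19 without a call. Rian rose from 16.8 ± 0.755 to 31.5 ± 9.45 in DKO (0.83 ± 0.21, adjusted p = 0.0433) and was at 19.95 ± 4.98 in WT. Meg3 was at 40.0 ± 4.35 in ICSI, 60.7 ± 21.9 in DKO, 52.9 ± 13.9 in IG and 43.7 ± 4.49 in WT, and Dlk1, a Notch ligand gene of the same cluster, at 28.9 ± 3.82, 28.3 ± 9.54, 24.0 ± 9.97 and 22.7 ± 6.80, with no call. Rtl1 and Tnnt3, at 3.55 ± 1.15 and 3.39 ± 1.24 in ICSI, passed in no placenta comparison, and Mrpl23 in no blastocyst comparison. The leukocyte gene Lsp1, next to H19, rose in WT by 1.21 ± 0.33, and DKO and H19 stood below WT by 1.01 and 1.12. Among cluster genes adjusted over the list alone, DKO stood above IG for Igf2 (7.61 on the log2 scale), Dio3 (2.05) and Dio3os (0.96, adjusted p = 0.0124), and above H19 for Mirg (0.97, adjusted p = 0.0135), Rian (0.78, adjusted p = 0.0135) and Meg3 (0.72, adjusted p = 0.0197). The last 3 did not pass over all genes (adjusted p = 0.206, 0.219 and 0.289). With 1 library left out at a time, the calls of Igf2, H19 and Dio3 held in WT against ICSI. That of Dio3os was lost without ICSI 3. The call of Lsp1 was lost in more than 1 such fit, among those without ICSI 1, 2 and 3. In IG against ICSI the calls of Igf2, Dio3 and Dio3os held, and H19 and Mirg each lost theirs in more than 1 such fit, as did Mirg and Rian in DKO against ICSI.

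**Figure D2:**
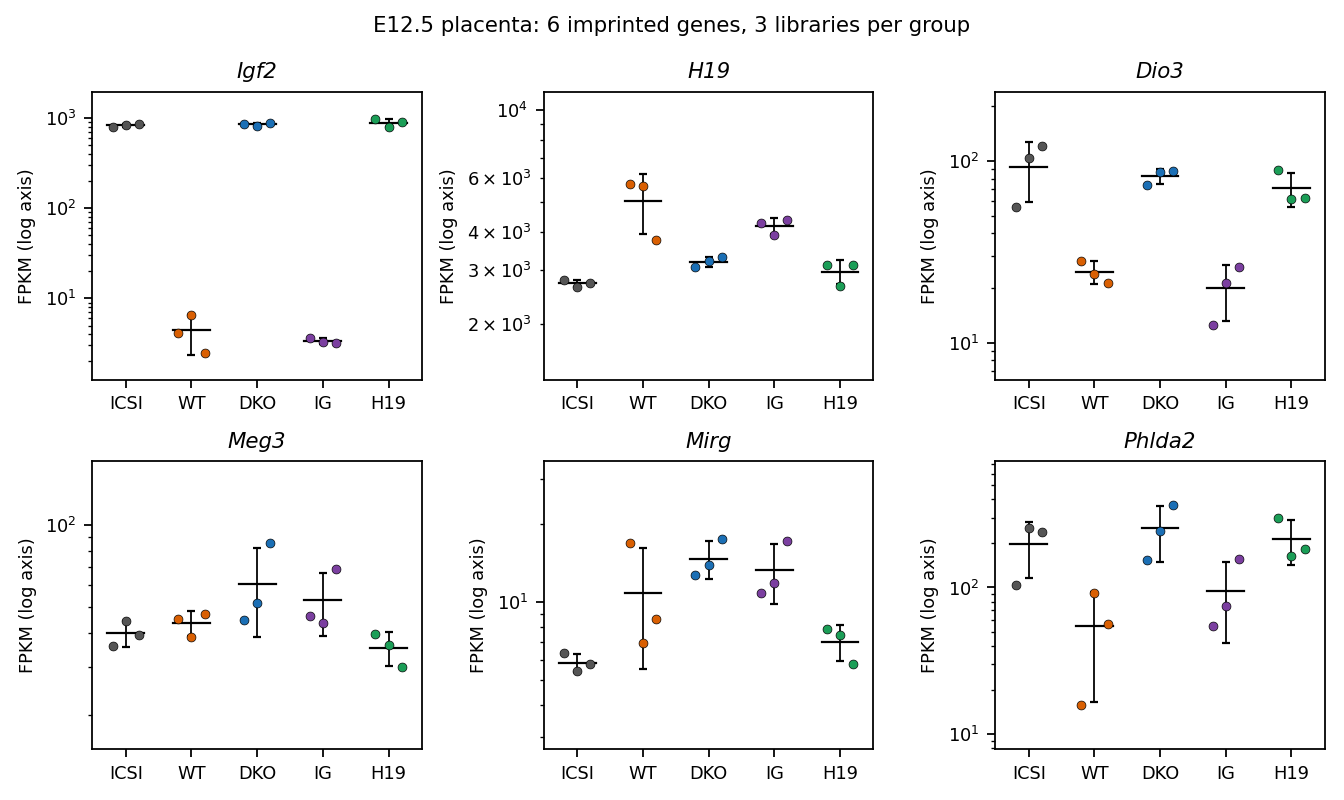
Levels of Igf2, H19, Dio3, Meg3, Mirg and Phlda2 in each placenta library, in FPKM on a log axis, by group; points are libraries (n = 3 per group), bars the group mean and error bars its SD. Igf2 lay at 4.43 ± 2.07 FPKM in WT and 834 ± 30.7 in ICSI.

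WT placentas were compared with ICSI placentas. Besides Igf2 and Dio3, the largest falls were those of Phlda2, from 199 ± 81.9 to 54.6 ± 38.2 FPKM (-2.06 ± 0.58), the calcium pump gene Atp2a3, from 31.1 ± 6.61 to 7.70 ± 1.09, and C1ql2, from 12.6 ± 2.72 to 2.61 ± 1.01. Cxcl14, a chemokine gene, rose from 9.40 ± 2.61 to 53.3 ± 17.9 (2.36 ± 0.39), the receptor partner gene Ramp3 from 20.9 ± 2.86 to 71.3 ± 17.7, and Akr1c18, whose enzyme inactivates progesterone, from 5.99 ± 2.33 to 27.2 ± 19.1. Sprr2h and Krtdap, genes of cornifying epithelium, rose by 2.62 and 1.89, and Guca2a, the guanylin gene, by 1.78; reads of the Sprr2 family are uncertain because its copies are alike. Labyrinth syncytiotrophoblast genes fell, 9 of 17 over all genes and 11 adjusted over the list alone (median -0.40; adjusted p = 9.78e-05, adjusted p = 0.677 with an estimated correlation), among them the transcription factor genes Tfeb, from 99.9 ± 7.41 to 42.8 ± 4.91, and Dlx3, from 86.8 ± 13.0 to 34.6 ± 8.62, and the fusion protein gene Syna, from 103 ± 10.5 to 39.8 ± 14.2. Cell cycle genes fell, 6 of 19 over all genes and 14 adjusted over the list alone (median -0.75; adjusted p = 9.78e-05, adjusted p = 0.701 with an estimated correlation). Cyclin gene Ccnb1 moved from 4.95 ± 0.329 to 2.11 ± 1.13. Genes of the maternal decidua rose, 7 of 16 over all genes and 9 adjusted over the list alone (median 0.60; adjusted p = 1.58e-05, adjusted p = 0.677 with an estimated correlation). Hoxa11 moved from 13.9 ± 2.65 to 29.2 ± 3.74 and Hand2 from 13.4 ± 2.56 to 29.0 ± 4.50; the decidua score was 5.80 ± 0.24 in WT and 5.17 ± 0.22 in ICSI.

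Stress genes were higher as a list in WT, 3 of 16 with 1 lower over all genes, and 6 with 2 lower adjusted over the list alone (adjusted p = 0.0221, adjusted p = 0.675 with an estimated correlation). Atf4, the transcription factor gene of the amino acid response, rose from 111 ± 7.24 to 190.0 ± 8.75 FPKM and its target Asns from 26.8 ± 3.15 to 52.4 ± 7.82. Paternally expressed imprinted genes were lower, 4 of 26 over all genes and 6 adjusted over the list alone (adjusted p = 0.0449, adjusted p = 0.701 with an estimated correlation), including Peg3 at 124 ± 9.45 against 185 ± 25.4 and Peg10, needed to form the placenta, at 611 ± 94.8 against 842 ± 49.7. Genes of DNA methylation were lower, 3 of 11, and 7 with 1 higher adjusted over the list alone (adjusted p = 0.0449, adjusted p = 0.701 with an estimated correlation). Uhrf1 was at 7.85 ± 2.12 against 15.3 ± 2.83. Genes of X inactivation were lower, 3 of 3 both ways (adjusted p = 0.0350, adjusted p = 0.677 with an estimated correlation), Xist at 34.7 ± 7.45 against 49.7 ± 2.75. Trophoblast giant cell genes were higher, 2 of 15, and 3 with 1 lower adjusted over the list alone (adjusted p = 0.0277, adjusted p = 0.701 with an estimated correlation). The peptide hormone gene Adm was at 120.3 ± 23.4 against 73.3 ± 16.1. Uterine natural killer cell genes (adjusted p = 0.00678, adjusted p = 0.701 with an estimated correlation) and yolk sac endoderm genes (adjusted p = 0.0449, adjusted p = 0.874 with an estimated correlation) were higher with no member past the threshold; without WT 3, DKO 3 and IG 1, chosen for these markers, the second call was lost. Afp was at 76.7 ± 130.0 against 1.51 ± 1.22, with its WT mean carried by WT 3. Primitive endoderm genes were higher, 1 of 19 over all genes and none adjusted over the list alone (adjusted p = 0.0449, adjusted p = 0.827 with an estimated correlation). The calls of the giant cell, yolk sac and primitive endoderm lists were lost when values were rescaled. Single left-out libraries decided the call of the heat shock list (WT 1), the paternally expressed list (ICSI 2 or WT 2 and 3), the DNA methylation list (ICSI 2 and 3 or WT 1 and 2), the X inactivation list (WT 2), the giant cell list (ICSI 2 or WT 1 and 2), the yolk sac endoderm list (ICSI 2 and 3 or WT 3) and the primitive endoderm list (ICSI 2 or WT 2 and 3).

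Of 12424 placental genes, 1678 differed between WT and ICSI, 540 higher and 1138 lower. With values rescaled, 1819 passed, 921 higher and 898 lower, and 1435 were the same genes, so the balance of directions depends on the scale. The count was 466 without ICSI 2, 298 without ICSI 3 and 560 without WT 3, and it was 443 without WT 3, DKO 3 and IG 1. When each library was left out in turn, the calls of Atp2a3, C1ql2, Cxcl14, Ramp3, Sprr2h, Tfeb, Dlx3, Syna, Atf4 and Asns held. That of Krtdap was lost without WT 3. Those of Phlda2, Akr1c18, Guca2a, Ccnb1, Hoxa11, Hand2, Peg3, Peg10, Uhrf1, Xist and Adm were each lost in more than 1 such fit.

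DKO placentas were compared with ICSI placentas. Genes of plasma proteins made by yolk sac endoderm and liver were the most increased. Afp, the alpha-fetoprotein gene, was at 992 ± 1292 against 1.51 ± 1.22 FPKM (7.88 ± 1.62), Apoa1 at 462 ± 608 against 0.697 ± 0.518 (7.20 ± 1.52) and Ttr, the transthyretin gene, at 159 ± 207 against 1.33 ± 0.301 (5.19 ± 1.18). Apoa2 and the albumin gene Alb rose by 6.30 and 3.88, and Spp2 was at 51.4 ± 68.5 with ICSI listed at 0. In the 3 DKO libraries Afp was 209, 283 and 2483 FPKM, and outside DKO it was 614 in IG 1, 227 in WT 3 and at most 52.9 elsewhere. Gdpd3, a lysophospholipase gene, fell from 55.3 ± 27.9 to 3.22 ± 4.87 (-4.23 ± 0.59), and Fosb, an immediate early gene, from 9.30 ± 1.51 to 1.92 ± 0.394. Slit1, Nov, Ear7 and Ceacam10 fell by 1.48 to 2.46; Ear7 and Ceacam10 have close copies and are uncertain.

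Yolk sac endoderm genes rose as a list, 9 of 17 over all genes and 17 adjusted over the list alone (median 3.62; adjusted p = 3.22e-09, adjusted p = 0.580 with an estimated correlation). Immediate early genes fell, 5 of 12 and 7 adjusted over the list alone (adjusted p = 3.22e-09, adjusted p = 0.0963 with an estimated correlation). Fos moved from 34.9 ± 4.96 to 14.1 ± 3.20 FPKM and Egr1 from 8.02 ± 0.525 to 2.46 ± 1.11. Genes of the hypoxia response fell, 4 of 16, and 7 with 1 higher adjusted over the list alone (adjusted p = 5.89e-07, adjusted p = 0.108 with an estimated correlation). Adm moved from 73.3 ± 16.1 to 35.4 ± 5.75 and the oxygen sensor gene Egln3 from 7.61 ± 2.02 to 2.70 ± 0.569. Labyrinth genes (adjusted p = 7.75e-04, adjusted p = 0.604 with an estimated correlation), decidua genes (adjusted p = 0.00594, adjusted p = 0.655 with an estimated correlation, 1 of 16 lower adjusted over the list alone) and fetal endothelium genes (adjusted p = 0.0219, adjusted p = 0.6997 with an estimated correlation) were lower without a member past the threshold over all genes. Spongiotrophoblast genes were lower, 1 of 25 and 5 adjusted over the list alone (adjusted p = 0.00235, adjusted p = 0.655 with an estimated correlation). The gene was Flt1, a receptor for vascular growth factor, at 146 ± 39.2 against 237 ± 25.02. Nutrient transporter genes were lower, 1 of 22 both ways (adjusted p = 0.00358, adjusted p = 0.580 with an estimated correlation). The gene was the fatty acid carrier Cd36, at 5.96 ± 0.340 against 8.59 ± 0.270. Stress genes were lower as a list with 1 of 16 higher both ways, the small heat shock gene Hspb1 at 141 ± 14.7 against 102 ± 13.3 (adjusted p = 0.0177, adjusted p = 0.255 with an estimated correlation). Erythroid genes were lower (adjusted p = 0.0219, adjusted p = 0.6997 with an estimated correlation), a call lost when values were rescaled. Leaving out 1 library ended the call of the decidua list (DKO 1), the fetal endothelium list (ICSI 3 or DKO 1) and the erythroid list (ICSI 1 and 3 or DKO 2 and 3).

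Between DKO and ICSI placentas 556 genes differed, 428 higher and 128 lower. Rescaled values gave 385 genes, 185 higher and 200 lower, so this balance too depends on the scale. The count was 54 without ICSI 1, 62 without ICSI 2, 103 without ICSI 3, 42 without DKO 2 and 50 without DKO 3 and 128 without WT 3, DKO 3 and IG 1. In fits that lacked 1 library, the calls of Gdpd3, Fosb, Slit1 and Fos held. Those of Afp, Apoa1, Ttr, Apoa2, Alb, Spp2, Nov, Ear7, Ceacam10, Egr1, Adm, Egln3, Flt1, Cd36 and Hspb1 were each lost in more than 1 such fit.

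IG placentas, made with injected cells that lacked the IG-DMR alone, were compared with ICSI. Besides Igf2 and Dio3, Gdpd3 fell from 55.3 ± 27.9 to 0.0909 ± 0.0588 FPKM (-5.54 ± 0.59), C1ql2 by 2.39 and Ceacam15 by 2.39. Hbb-bs, an adult haemoglobin gene with close copies, was at 30.3 ± 8.56 against 142 ± 51.5. Cpe, a prohormone-processing enzyme gene, rose from 29.2 ± 2.91 to 79.5 ± 15.1, the stress-response factor gene Atf5 from 16.6 ± 2.21 to 35.9 ± 3.22, Ramp3 by 1.15 and Cxcl14 by 1.49. Prl8a6, a prolactin-family gene, and Cbx7, a Polycomb gene, rose by 1.56 and 1.15. Stress genes rose, 4 of 16 and 5 adjusted over the list alone (adjusted p = 3.57e-05, adjusted p = 0.0340 with an estimated correlation). Atf4 was at 159.9 ± 2.16 against 111 ± 7.24 and the heat shock genes Hspa1a, which has a near-identical copy, at 8.01 ± 1.002 against 4.38 ± 0.131 and Hsph1 at 67.4 ± 3.71 against 47.2 ± 3.44. Labyrinth genes fell, 4 of 17 and 5 adjusted over the list alone (median -0.34; adjusted p = 7.23e-05, adjusted p = 0.672 with an estimated correlation). Tfeb was at 40.3 ± 5.65 against 99.9 ± 7.41 and Dlx3 at 36.3 ± 3.38 against 86.8 ± 13.0.

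Cell cycle genes were lower in IG, 1 of 19 and 2 adjusted over the list alone (adjusted p = 1.23e-04, adjusted p = 0.672 with an estimated correlation). The gene was Cdc20, which drives exit from mitosis, at 11.1 ± 4.48 against 21.3 ± 5.48 FPKM. Decidua genes were higher, 5 of 16 adjusted over the list alone (adjusted p = 4.19e-05, adjusted p = 0.672 with an estimated correlation), with a score of 5.66 ± 0.29. Erythroid genes were higher, 1 of 16 and 2 adjusted over the list alone (adjusted p = 0.00818, adjusted p = 0.672 with an estimated correlation). The gene was the red cell membrane gene Rhag, at 2.66 ± 1.78 against 0.461 ± 0.314. Genes of macrophages (adjusted p = 4.79e-04, adjusted p = 0.672 with an estimated correlation), uterine natural killer cells (adjusted p = 0.00677, adjusted p = 0.672 with an estimated correlation), yolk sac endoderm (adjusted p = 4.19e-05, adjusted p = 0.672 with an estimated correlation) and primitive endoderm (adjusted p = 0.0225, adjusted p = 0.672 with an estimated correlation) were higher with no member past the threshold, and the last call was lost when values were rescaled. With 1 library fewer the call was lost for the erythroid list (ICSI 2 or IG 3), the uterine natural killer cell list (IG 3), the yolk sac endoderm list (IG 1) and the primitive endoderm list (ICSI 2 or IG 1). In all 647 genes differed, 215 higher and 432 lower. Of the 647, 68 lie in the raised chromosome 5 run (Rfc2 to Rfc3) and 14 in a raised chromosome 7 run (Zfp568 to Usf2). With values rescaled, 713 passed, 334 higher and 379 lower. The count was 253 without ICSI 2, 221 without ICSI 3, 339 without IG 1 and 284 without IG 2. Over the fits lacking 1 library each, the calls of Gdpd3, C1ql2, Ceacam15, Cpe, Atf5, Ramp3, Atf4, Hspa1a, Hsph1, Tfeb and Dlx3 held. Those of Hbb-bs, Cxcl14, Prl8a6, Cbx7, Cdc20 and Rhag were each lost in more than 1 such fit.

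H19 placentas, which lack the H19 region alone, were compared with ICSI. Gdpd3 fell from 55.3 ± 27.9 to 0.216 ± 0.0974 FPKM (-5.38 ± 0.59), the neuronal adhesion gene Lrrn4 from 14.1 ± 2.47 to 2.53 ± 0.766 and the endosome gene Rab11fip4 from 9.72 ± 0.979 to 3.89 ± 1.15. Foxo3, a transcription factor gene of insulin signalling, Clic5 and the splicing factor gene Esrp1 fell by 0.68 to 0.77. Phb, the prohibitin gene, rose from 11.9 ± 0.380 to 21.7 ± 0.839 (0.82 ± 0.11), the lipid droplet gene Plin2 from 128 ± 1.05 to 200.3 ± 21.4 and Hspa1a from 4.38 ± 0.131 to 8.61 ± 1.08. Myl12a, a myosin light chain gene, Tmx1 and Fam117a rose by 0.67 to 0.72. Stress genes were higher, 1 of 16 and 3 adjusted over the list alone (adjusted p = 0.0241, adjusted p = 0.332 with an estimated correlation). This call was lost without H19 2. Of 12424 genes 21 passed, 11 higher and 10 lower. Of the 21, 4 lie in a raised chromosome 11 run (Itga3 to Snx11), which may include Phb and Fam117a. Without ICSI 1, 2 or 3 in turn, the count was 8, 3 and 8. Without H19 2 or 3 it was 5. It was 56 (22 higher, 34 lower) with values rescaled, 37 without WT 3, DKO 3 and IG 1, and 1026 with library weights. With 1 library left out at a time, the calls of Gdpd3 and Tmx1 held. That of Plin2 was lost without ICSI 2. Those of Lrrn4, Rab11fip4, Foxo3, Clic5, Esrp1, Phb, Hspa1a, Myl12a and Fam117a were each lost in more than 1 such fit.

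DKO placentas were compared with WT placentas, from other injected cells, so deletions and cell line are not separated. Igf2 rose from 4.43 ± 2.07 to 859 ± 35.9 FPKM (7.38 ± 0.19), Dio3 from 24.6 ± 3.498 to 82.7 ± 7.96 (1.72 ± 0.28), and H19 fell from 5059.6 ± 1111 to 3203 ± 125 (-0.63 ± 0.17). Apoa1, Apoa2, Alb and the fetuin gene Ahsg rose by 3.31 to 5.24. Cxcl14 fell from 53.3 ± 17.9 to 7.86 ± 6.23, the retinoid-binding gene Crabp1 from 85.8 ± 41.4 to 18.0 ± 5.26, and the crystallin chaperone gene Cryab from 351 ± 149 to 93.5 ± 29.5. Gdpd3, Sprr2h and Tacstd2 fell by 2.001 to 2.81. Cell cycle genes rose, 16 of 19 and 18 adjusted over the list alone (median 1.03; adjusted p = 1.59e-07, adjusted p = 0.477 with an estimated correlation). Ccna2 moved from 10.7 ± 3.20 to 29.0 ± 2.41 and the replication helicase gene Mcm2 from 10.1 ± 1.76 to 22.8 ± 2.27. Decidua genes fell, 11 of 16 both ways (median -1.09; adjusted p = 1.85e-11, adjusted p = 0.130 with an estimated correlation). Hoxa10 moved from 44.9 ± 5.92 to 19.4 ± 6.05, and the score was 4.89 ± 0.38 in DKO and 5.80 ± 0.24 in WT. Stress genes fell, 7 of 16 with 1 higher both ways (adjusted p = 2.47e-06, adjusted p = 0.0239 with an estimated correlation). Atf4 moved from 190.0 ± 8.75 to 103 ± 4.08 and Trib3 from 8.33 ± 2.84 to 3.73 ± 0.343.

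Genes of the hypoxia response were lower in DKO than in WT, 7 of 16, and 8 with 3 higher adjusted over the list alone (adjusted p = 2.66e-05, adjusted p = 0.130 with an estimated correlation). Adm was at 35.4 ± 5.75 against 120.3 ± 23.4 FPKM and the hexokinase gene Hk2 at 12.2 ± 0.423 against 25.4 ± 1.67. Immediate early genes were lower, 5 of 12 and 8 adjusted over the list alone (adjusted p = 9.29e-08, adjusted p = 0.0822 with an estimated correlation). Ier3 was at 32.8 ± 2.78 against 79.9 ± 12.8. Yolk sac endoderm genes were higher, 6 of 17 and 13 adjusted over the list alone (adjusted p = 4.55e-04, adjusted p = 0.592 with an estimated correlation). Giant cell genes were lower, 2 of 15 and 3 adjusted over the list alone (adjusted p = 1.66e-04, adjusted p = 0.318 with an estimated correlation), and fetal endothelium genes were lower, 1 of 15 both ways (adjusted p = 2.66e-05, adjusted p = 0.349 with an estimated correlation). The gene was the junction gene Cldn5, at 20.1 ± 4.50 against 36.1 ± 8.55. Genes of erythroid cells (adjusted p = 0.00236, adjusted p = 0.570 with an estimated correlation) and uterine natural killer cells (adjusted p = 0.00349, adjusted p = 0.579 with an estimated correlation) were lower with no member past the threshold, and both calls were lost when values were rescaled. Leaving out 1 library ended the call of the uterine natural killer cell list (DKO 1). In all 2263 genes differed, 1824 higher and 439 lower. The median of all genes stood at 0.12, and with values rescaled 1473 genes passed, 714 higher and 759 lower, of which 1153 were the same genes. The count was 1163 without WT 3, 1269 without DKO 1, 1008 without DKO 2 and 1288 without DKO 3, and 439 without WT 3, DKO 3 and IG 1. When each library was left out in turn, the calls of Igf2, Dio3, Cxcl14, Crabp1, Cryab, Gdpd3, Sprr2h, Tacstd2, Ccna2, Mcm2, Hoxa10, Atf4, Trib3, Adm, Hk2 and Ier3 held. Those of H19, Apoa1, Apoa2, Alb, Ahsg and Cldn5 were each lost in more than 1 such fit.

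The single deletions were each compared with WT placentas, again from other injected cells. Mmp1a, a collagenase gene, was higher in IG at 36.5 ± 18.96 against 6.92 ± 2.89 FPKM, Flt1 at 381 ± 32.0 against 155 ± 36.1 (1.31 ± 0.19), Syna at 81.5 ± 5.44 against 39.8 ± 14.2 and Hsph1 at 67.4 ± 3.71 against 34.5 ± 2.30, while Slit1 and the heat-induced gene Zfand2a rose by 1.200 and 0.90. Gdpd3 fell by 4.11, Sprr2f and the lipocalin gene Lcn2 by 2.56 and 2.29, the secretin gene Sct from 4052 ± 608 to 2116 ± 445, and Fdx1, an electron carrier gene of steroid synthesis, and Lbh by 0.83 and 0.69. Igf2 was at 3.39 ± 0.256 against 4.43 ± 2.07 and Dio3 at 19.96 ± 6.81 against 24.6 ± 3.498, neither past the threshold (adjusted p = 0.605 and 0.607). Giant cell genes were lower, 3 of 15 adjusted over the list alone (adjusted p = 3.64e-04, adjusted p = 0.743 with an estimated correlation), and trophectoderm genes were lower, 1 of 20 and 2 adjusted over the list alone (adjusted p = 0.00901, adjusted p = 0.377 with an estimated correlation). The gene was Krt19, at 398 ± 27.5 against 603 ± 59.6. With WT 1 or IG 3 left out, both list calls were lost. In all 123 genes differed, 90 higher and 33 lower. Of the 123, 55 lie in 1 run of 142 neighbours on chromosome 5 (Wbscr16 to Rfc3), which may include Flt1, Hsph1 and Zfand2a. The count was 200 without WT 1, 62 without WT 3, 58 without IG 1, 39 without IG 2 and 60 without IG 3, 54 without WT 3, DKO 3 and IG 1, while IG 3 had a small RNA share of 23.9%. In fits that lacked 1 library, the calls of Flt1, Hsph1, Zfand2a, Gdpd3, Sprr2f and Lbh held. The calls of Mmp1a, Syna, Slit1, Lcn2, Sct, Fdx1 and Krt19 were each lost in more than 1 such fit, among those without WT 1, 2 and 3 and IG 1, 2 and 3.

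In H19 against WT, Igf2 rose from 4.43 ± 2.07 to 895 ± 95.4 FPKM (7.43 ± 0.19), Dio3 by 1.48 and Phlda2 from 54.6 ± 38.2 to 216 ± 73.3, and H19 fell from 5059.6 ± 1111 to 2971 ± 270.3. Fgfbp1, whose protein releases growth factors from the matrix, Mmp1a and the cyclin E gene Ccne1 rose by 1.58 to 1.99. Gdpd3, Cxcl14, the neuropeptide gene Npb, 1600027J07Rik, Ear1 and Krtdap fell by 2.01 to 3.96. Cell cycle genes rose, 12 of 19 and 18 adjusted over the list alone (median 0.94; adjusted p = 1.67e-07, adjusted p = 0.625 with an estimated correlation). Ccna2 was at 25.9 ± 5.83 against 10.7 ± 3.20. Labyrinth genes rose, 6 of 17 and 10 adjusted over the list alone (adjusted p = 0.00116, adjusted p = 0.625 with an estimated correlation). Dlx3 was at 90.9 ± 26.1 against 34.6 ± 8.62 and the glucose carrier gene Slc2a1 at 572 ± 45.3 against 439 ± 21.5. Decidua genes fell, 8 of 16 and 10 adjusted over the list alone (median -0.92; adjusted p = 1.28e-09, adjusted p = 0.390 with an estimated correlation). Hoxa10 was at 15.8 ± 2.42 against 44.9 ± 5.92 and the muscle filament gene Des at 135 ± 32.7 against 489.6 ± 116. Targets of p53 were lower, 3 of 15 with 1 higher both ways (adjusted p = 0.0116, adjusted p = 0.390 with an estimated correlation). Cdkn1a was at 16.00 ± 1.40 against 30.2 ± 3.47. Giant cell genes, 2 of 15 both ways (adjusted p = 0.0114, adjusted p = 0.625 with an estimated correlation), and fetal endothelium genes, 2 of 15 both ways (adjusted p = 0.00146, adjusted p = 0.625 with an estimated correlation), were lower, as were uterine natural killer cell genes with no member past the threshold (adjusted p = 0.00146, adjusted p = 0.680 with an estimated correlation). Single left-out libraries decided the call of the giant cell list (WT 1). In all 1695 genes differed, 1128 higher and 567 lower. Rescaled values gave 1619 genes, 734 higher and 885 lower. The count was 577 without WT 3, 271 without H19 1 and 891 without H19 3, and 547 without WT 3, DKO 3 and IG 1. Over the fits lacking 1 library each, the calls of Igf2, Dio3, Gdpd3, Cxcl14, Ear1, Krtdap, Dlx3, Hoxa10, Des and Cdkn1a held. Those of H19, Ccne1 and Slc2a1 were lost without H19 1. The calls of Phlda2, Fgfbp1, Mmp1a, Npb, 1600027J07Rik and Ccna2 were each lost in more than 1 such fit, among those without WT 1, 2 and 3 and H19 1, 2 and 3.

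**Figure D3:**
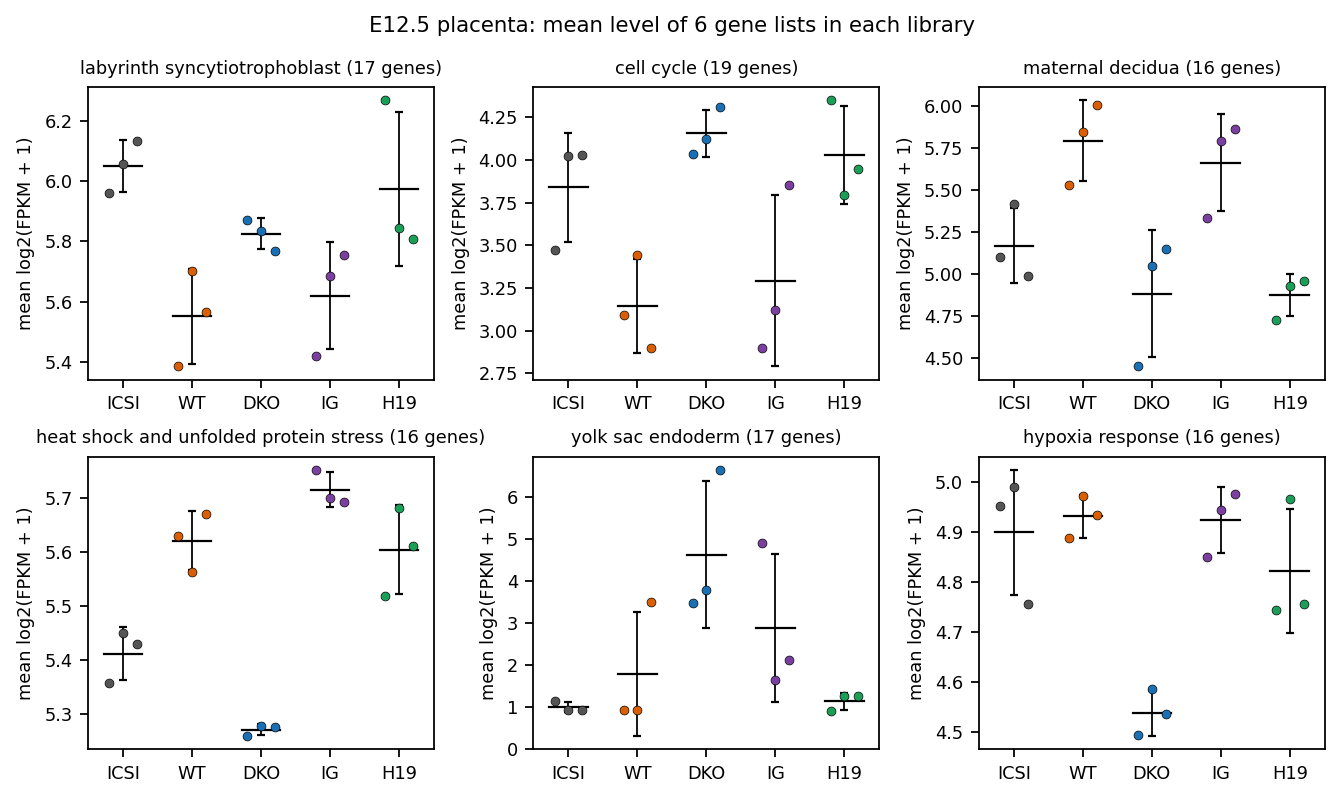
Mean log2(FPKM + 1) over the measured members of 6 gene lists in each placenta library, by group; points are libraries (n = 3 per group), bars the group mean and error bars its SD. The cell cycle score was 3.14 ± 0.28 in WT and 3.84 ± 0.32 in ICSI.

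The genes that differed between WT and ICSI placentas were followed into the deletion placentas. Of the 1678, 735 (43.8%) also differed between DKO and WT in the opposite direction, 565 lower in WT and higher in DKO and 170 the other way, and 3 differed in the same direction. In H19 placentas 731 (43.6%) did so, 496 and 235, and in IG placentas 48 (2.86%), 27 and 21. Igf2 and Dio3 were among them in DKO and H19, and neither was called in IG against WT. Independent lists of these sizes would share 167 and 19.1 genes in DKO and 103 and 24.6 in H19 and 8.24 and 1.43 in IG. Over all genes, 74.2% had opposite signs in DKO, 78.3% in H19 and 68.9% in IG, and simulated unchanged groups that share WT libraries gave 66.7%, 66.5% and 66.7%, and no gene moved back in 20 such simulations, where no gene was changed. With too few WT placentas to split between the comparisons, part of the excess may come from sharing them. The decidua score was 5.80 ± 0.24 in WT, 5.66 ± 0.29 in IG, 5.17 ± 0.22 in ICSI, 4.89 ± 0.38 in DKO and 4.87 ± 0.13 in H19. With the score in the fit, 95 of 1671 genes outside that list still passed in WT against ICSI, and its part in the moves back was not tested. In the blastocyst, 0 of 13 ICM genes and 1 of 68 TE genes, 3830417A13Rik, differed in the opposite direction in DKO against WT, where limma called 2 and 1 genes and 732 and 538 had an unadjusted p under 0.05.

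**Figure D4:**
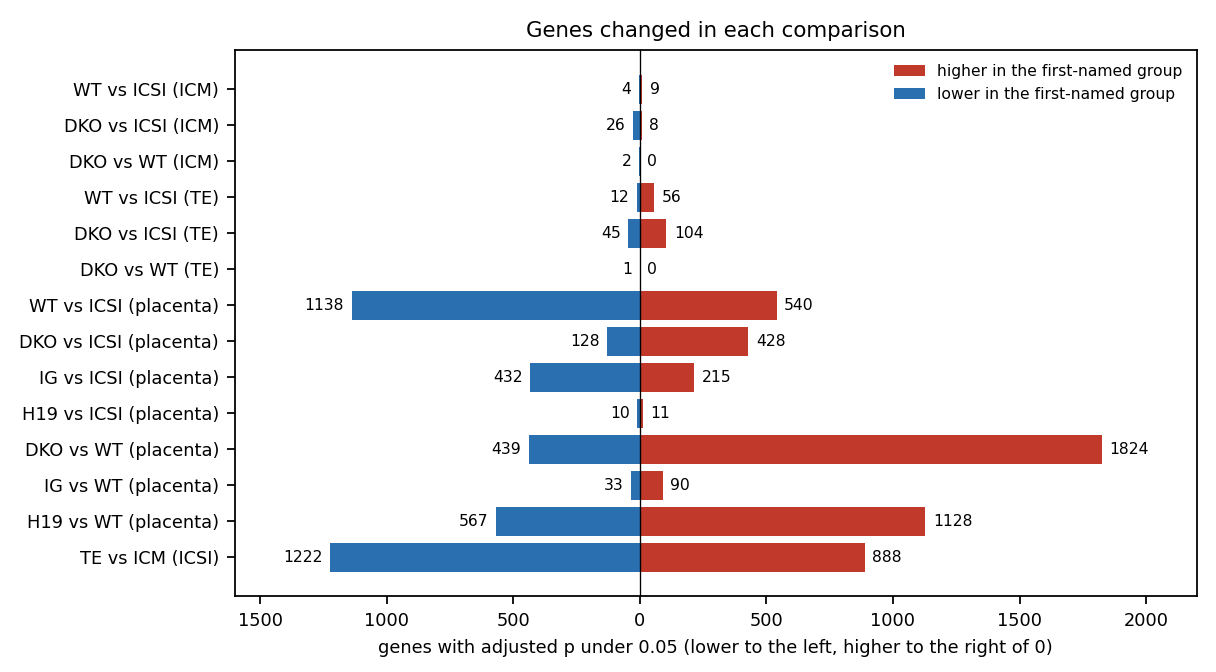
Number of genes past the threshold in each comparison on the horizontal axis, those lower in the first-named group to the left of 0 and those higher to the right. Bars reach 1824 higher and 439 lower in DKO against WT in the placenta.

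Runs of neighbouring genes that shifted together were sought after the counts had been seen, and 28 were found over all comparisons, of which some are described. On chromosome 5, 138 genes from Rfc2 to Rfc3 stood 0.46 ± 0.04 higher in IG placentas than in ICSI on the log2 scale (mean and SD over 3 libraries of the median over genes), 96.4% of them in that direction, with 68 called. Every other placenta library lay between -0.03 and 0.05 on this score. On chromosome 11, 16 genes from Itga3 to Snx11 stood 0.46 ± 0.02 higher in H19 placentas. Those of them measured in the blastocyst stood 0.43 ± 0.09 higher in the WT ICM and 0.63 ± 0.12 in the WT TE, but -0.14 ± 0.16 and 0.00 ± 0.14 in DKO and -0.01 ± 0.14 in WT placentas. On chromosome 9, genes from 2310009A05Rik to Lysmd2 stood higher in DKO in the ICM (0.54 ± 0.09), the TE (0.50 ± 0.12) and the placenta (0.57 ± 0.01). On chromosome 7, 23 genes from Phrf1 to Cttn, the stretch that holds Cd81, Phlda2 and Nap1l4, stood 0.72 ± 0.16 higher in the WT TE and 0.06 ± 0.11 in the DKO TE, and 23 genes from Zfp568 to Usf2 stood 0.55 ± 0.07 higher in IG placentas, 0.20 ± 0.01 in WT, 0.25 ± 0.05 in DKO and 0.11 ± 0.02 in H19. On chromosome 15, 12 genes from Krt7 to Pfdn5 stood 0.56 ± 0.05 higher in WT and 0.44 ± 0.10 in IG placentas, against 0.08 ± 0.04 in DKO and 0.01 ± 0.06 in H19.

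**Figure D5:**
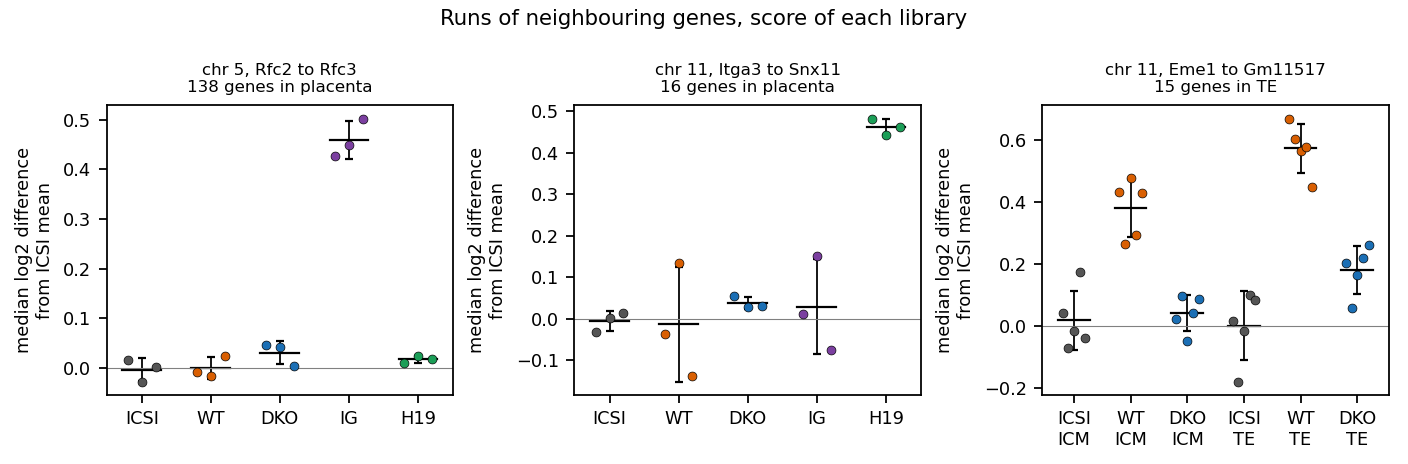
Median log2 difference from the ICSI mean over the genes of 3 runs of neighbouring genes, per library and by group; points are libraries and bars the group mean with its SD. The IG placentas lie between 0.43 and 0.50 in the chromosome 5 run.

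The sex of the embryos was read from Xist, the RNA that silences an X chromosome, and from 9 Y-linked genes. The highest Y-linked level in any of the 45 libraries was 0.178 FPKM. Xist stood at 17.5 to 94.2 FPKM in the blastocyst libraries and at 26.6 to 52.3 in the placentas. Among the tested lists, 5 were called in no comparison. Their lowest adjusted p-values were 0.271 for the H19-Igf2 cluster, 0.0735 for the Dlk1-Dio3 cluster, 0.168 for fetal mesenchyme and pericytes, 0.0844 for germline genes silenced by DNA methylation and 0.221 for oocyte and maternal-effect genes.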

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

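The tests of spread, of differences between lineages, of other splits, of decidua and of the shared state were fixed before their results were seen, while the test of rescaled values in the third paragraph was chosen afterwards. Within each group of 5 libraries, a library was singled out where its gap to the next exceeded 0.71 of the group's range. This happened in 32 of 271 gene groups and 5 of 24 groups of library measures. Chance gives about 1 in 20 for normal values, while its rate here was not measured. In the ICM the highest library stood apart for Snora23 (ICSI 2, gap over range 1), Dmgdh (DKO 5, 0.823), Tspan8 (WT 2, 0.743), Slc38a1 (WT 2, 0.759), Wfdc15a (WT 3, 0.934), Fgf4 (WT 4, 0.7104), Hs3st1 (ICSI 1, 0.839, and WT 3, 0.862), Endog (DKO 1, 0.774), Foxa2 (DKO 1, 1) and Gdf3 (ICSI 2, 0.769). In the ICSI TE it did so for Meg3 (ICSI 2, 0.752), Phlda2 (ICSI 3, 0.831), Gm3286 (ICSI 1, 0.827), Klk7 (ICSI 2, 0.778), Tdgf1 (ICSI 4, 0.964), Timp1 (ICSI 2, 0.857), Pyy (ICSI 2, 1), Fgf4 (ICSI 4, 0.967), Sparc (ICSI 2, 0.881) and Zfp57 (ICSI 4, 0.862). In the WT TE it did so for Phlda2 (WT 2, 0.817, at 264 FPKM against 50.05 in the next), Reep1 (WT 1, 0.821), Dusp6 (WT 4, 0.724), Wfdc15a (WT 5, 0.822), Trib3 (WT 3, 0.787) and Entpd1 (WT 4, 0.858). In the DKO TE these were Meg3 (DKO 4, 0.776), Bhmt (DKO 5, 0.781) and Laptm5 (DKO 5, 0.836). The lowest library stood apart for Mus81 (WT 2 of the TE, 0.795) and Mrpl23 (DKO 2 of the TE, 0.8300). ICSI 4 of the ICM had few genes at 1 FPKM or more (9180, 0.750) and 20.01% of its FPKM in its top 10 genes (0.784). WT 5 of the TE had a low relative depth (0.817) and a top-10 share of 19.5% (0.860), and DKO 1 of the TE a top-10 share of 11.8% (0.896).

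The WT against ICSI changes of trophectoderm and labyrinth genes differed between lineages. As TE minus ICM the medians were 1.57 and 0.55 (adjusted p = 1.08e-07 and 0.0325, 0.573 for both with an estimated correlation). Without the ICM and TE libraries in doubt, the trophectoderm value was 0.99 and no longer passed, but 2 ICSI ICM libraries were in doubt for high trophectoderm markers, so leaving them out lowers this value by construction.

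For the 1678 placenta genes that differed between WT and ICSI, more maternal decidua in WT libraries is argued against as the whole cause, since with the decidua score in the fit the 1671 genes outside that list kept their sign and a median of 0.891 of their log2 change. Only 95 still passed, because score and group overlap and the SE rose by a median factor of 1.34; Igf2 moved from -7.34 ± 0.19 to -7.20 and the cell cycle median from -0.75 to -1.01. Scaling between libraries is argued against by the 85.5% of these genes that still passed with rescaled values. A state shared by the groups low in Igf2 cannot be told apart from other differences between the groups: 73.4% of the genes had the same sign in IG minus H19, between the bounds set for it, against 62.2% of all tested genes and 52.8% in DKO minus H19, where 33 genes differed and not 1694; with rescaled values the 2 shares were 70.3% and 61.7%. Differences between the injected cell lines stay open, untested.

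Other splits of the same libraries were counted, 100 drawn per blastocyst comparison. Chance is argued against for WT against ICSI in the ICM (13 genes, at most 2 in another split, 1 split as large with the real one counted) and in the TE (68 and 58, 1 split) and for TE against ICM (2110 and 699, 1 split). With 100 splits a share cannot go below 1 in 100, and more than 1 comparison was tried, so chance is not excluded. Few splits were as large for DKO against ICSI in the ICM (34 genes, 3 splits) and TE (149, 2 splits). The same held for DKO against WT in the ICM (2 genes, 3 splits). As others called up to 921, 214 and 3 genes, chance is unlikely but not excluded. Chance cannot be excluded for DKO against WT in the TE (1 gene, up to 69 elsewhere, 11 splits), while for the difference between lineages a real count of 0 by limma (536 at an unadjusted p under 0.05) is met by all 100 splits whatever they hold (up to 91), which says nothing about chance. The splits with 921, 69 and 91 genes point to a structure of the samples other than their groups. In the placenta, 10 splits are too few for a share under 0.05. The real counts and the highest others were 1678 and 2 for WT, 556 and 2 for DKO, 647 and 0 for IG and 21 and 0 for H19 against ICSI, and 2263 and 0 for DKO, 123 and 1 for IG and 1695 and 1 for H19 against WT.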

How the results depend on the processing

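Leaving out the libraries in doubt was chosen after the data were seen. With 1 library left out, counts moved by over 1.5 times in 68 of 132 cases. They ran from 0 to 34 for WT against ICSI, 1 to 341 for DKO against ICSI and 1 to 4 for DKO against WT in the ICM, and from 10 to 95, 21 to 983 and 1 to 2 in the TE. In the placenta they ran from 298 to 1959 for WT, 42 to 423 for DKO, 221 to 596 for IG and 3 to 20 for H19 against ICSI, and from 1008 to 2542 for DKO, 39 to 200 for IG and 271 to 1884 for H19 against WT. TE against ICM stayed between 1586 and 2210, and the difference between lineages between 0 and 2 (limma; 536 at an unadjusted p under 0.05 in the reported fit). A placenta group then has 2 libraries, whose spread limma pools with the other groups. Beyond fewer libraries, the cause was not tested.

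With no filter on low values more genes were tested, and the counts for WT and DKO against ICSI were 0 and 2 in the ICM (limma; 1493 and 1920 at an unadjusted p under 0.05), 25 and 44 in the TE, 307 for DKO and 13 for H19 against ICSI in the placenta, and 1 for the difference between lineages. Library weights gave 60, 165 and 4 genes in the ICM, 214, 1428 and 24 in the TE, 2378, 4726 and 1026 for DKO, IG and H19 against ICSI in the placenta, and 317 and 642 for IG and H19 against WT. A pseudocount of 0.1 FPKM gave 3 for DKO against ICSI and 4 for DKO against WT in the ICM. Rescaling gave 52 for DKO against ICSI in the ICM, 105 for WT against ICSI in the TE, 56 for H19 against ICSI and 1473 for DKO against WT in the placenta. The cause was not tested for these. With the replicate number as a replicate block, DKO against WT in the ICM gave 1 and H19 against ICSI 34, and the other 13 counts stayed within 1.5 times. The labels pair no samples by number; as a hint from the data, each library correlated best with its own number in 3 of 3 between DKO and WT placentas (0.0979 to 0.305), where the replicate block gave 2185 genes, in 5 of 5 between DKO ICM and TE, which were not compared, and in 4 of 5 between ICSI ICM and TE, where it gave 2536.

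Without the libraries in doubt, the ICM counts were 0, 0 and 1 (limma; 401, 807 and 951 at an unadjusted p under 0.05), and the 1 gene was neither Ldha nor Atat1. In the placenta WT, DKO and H19 against ICSI gave 443, 128 and 37, and DKO, IG and H19 against WT gave 439, 54 and 547. Without IG 3 alone, IG against WT gave 60. In 2 list results the call was lost and camera, which sets a list against all other genes, gave the other direction. The trophectoderm median of DKO against WT in the ICM was -0.58 (adjusted p = 0.415), and the yolk sac median of WT against ICSI in the placenta stayed above 0 at 0.0960 (adjusted p = 0.976). Libraries had been left out for these same markers, which favours both moves, and groups then hold as few as 2 libraries. With WT libraries split between the comparisons, the count of TE genes that moved back in DKO was 0 (limma), against 1; with 3 WT placentas such a split was not run.

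With a correlation estimated per list, 6 of 81 list calls held, since members that vary together carry less evidence. The other list calls held in 72 of 81 cases with rescaling, 75 with no filter, 78 with a pseudocount of 0.1 FPKM, 77 with weights, 77 with the block, 62 without the libraries in doubt, 7 of 11 without IG 3 and 565 of 626 with 1 library left out. Named genes kept their side of the threshold in 3863 of 4575 such fits, with 647 calls lost and 65 gained, in 578 of 598 with rescaling, 574 of 598 with a pseudocount of 0.1 FPKM, 532 of 576 with the block, 492 of 576 with weights, 469 of 576 with no filter, 440 of 567 without the libraries in doubt and 76 of 89 without IG 3. How far depth or spread between libraries limits recovery of simulated changes in the ICM was not tested.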

Other observations

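The tests of runs of neighbouring genes and of yolk sac tissue were written before their results, on patterns that had been noticed in these data, while the test of the double deletion alone and the look at chromosome 11 in WT placentas were chosen after the result was seen. Stretches of neighbouring genes shifted together on chromosome 5 in IG placentas (Rfc2 to Rfc3) and on chromosome 11 in WT blastocysts and H19 placentas. Neighbours that vary together in every group are argued against, as the correlation within groups lay at percentile 30.0 of windows of equal length on chromosome 5 and at percentile 13.9 on chromosome 11. A changed copy number in the injected cells, 1 factor for every gene, cannot be told apart from other causes. On chromosome 5 the spread of the changes was 0.985 of that of other genes, but in the libraries the run was chosen from; on chromosome 11, 8 genes of the H19 run stood 0.70 higher in the WT TE with a spread ratio of 0.341, while WT placentas lacked the shift (-0.01 ± 0.14), which goes against a copy change in all WT cells. No DNA was measured, and a regional change of chromatin stays open.

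The other pattern is the yolk sac endoderm markers in DKO placentas, such as Afp at 209, 283 and 2483 FPKM and Ttr at 29.0, 49.8 and 397. Yolk sac tissue carried into some libraries may be the source, since over the 5 libraries that had it (the DKO libraries, IG 1 and WT 3), the share of each of 13 abundant markers in their sum varied by a median factor of 1.48 (1.02 to 4.66). The double deletion alone is argued against, as 2 libraries outside DKO, IG 1 and WT 3, scored above the lowest DKO library. Expression by cells of the placenta itself and a difference in dissection stay open. The list was fixed in advance, and of its 17 measured members 5 averaged 1 FPKM or more in ICSI placentas and 2 are in another list.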
